A study of Mus musculus with 6 samples.

How the data were processed

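RNA sequencing was analysed for 6 tumours of the mouse ovarian cancer cell line HM1, 3 labelled shControl and 3 labelled shST3GAL3, and samples were grouped by their titles. Per the labels' protocols, total RNA was extracted with TRIzol, treated with DNase I and made into Illumina libraries. The deposited values are TPM, a relative transcript abundance corrected for gene length, given per gene with 2 decimals. The unit was judged from the values, which are not whole and sum to between 999999 and 1000001 in each library. The submitters' processing notes name fastp, HISAT, RSEM and the genome build GRCm39, with no versions. The annotation release, the parameters and the strand setting are not given in the sources used here. Each file held 57462 genes, 482 of them assembled loci without an Ensembl gene ID. They keep no read number, so depth is unknown, no counting interval or detection floor was given, and precision rests on the replicates alone. TPM is relative to the library's own total, so a rise in a few abundant transcripts lowers the values of all others. Reads from near-identical genes could have been divided between them in the authors' estimation, which leaves such genes uncertain.

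A test of counts had been planned first. Since the files held TPM, the alternative written beforehand for that case was used, limma 3.58.1 in R 4.3.3 with a mean-variance trend on log2(TPM + 1). Genes with a TPM of at least 1 in 3 or more libraries were kept, 14207 in all, and the model held the group alone. P-values were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Fold changes are on the log2(TPM + 1) scale, which understates the change of genes with low values. Errors are SD over n = 3 for TPM and the moderated SE for log2 fold changes, and pairs of TPM values give shControl first.

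For gene groups, 33 lists with 398 genes in all were fixed before the data were examined, covering immune and stromal cell types, interferon responses, antigen presentation, sialic acid biology, tumour cell programmes, neighbouring tissues and handling stress. The genes Ctla4 and Siglech stood in more than 1 list. Lists with 3 or more tested genes were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. Members were also counted after adjustment over the list alone. Where a symbol occurred more than once, the entry with the highest mean was used. Chromosome and biotype were taken by gene ID from GENCODE M21, which held 95.8% of the tested IDs. That annotation is on the build GRCm38, another than that of the files, so no coordinates were given. Transcript sequences of GENCODE M21 were compared with blastn 2.17.0.

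The genes named in the text followed a rule set before the data were examined. They were St3gal3, in each direction the 5 genes with the smallest p where none passed (predicted genes and pseudogenes left out), up to 4 members of each list with the smallest p, the St3gal family, and Siglece, Cd8a, Cd274, Pdcd1 and Adgre1. The text gives a selection of these, and names others as chosen after their values were seen.

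The procedure was tested on simulated data with the means and spread of the 14207 genes, with 200 changed genes in each of 20 runs. Of changes of log2 size 1, 60.2% were recovered, and of log2 size 2, 87.8%, with 4.9% false genes among the calls. A planted list of 15 genes raised by 0.5 was found by camera in 20 of 20 runs, and 1% of unchanged lists had a p under 0.05. The simulated genes varied independently, unlike genes in tissue.

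Alternatives were another pseudocount, other filters, protein-coding genes alone, the replicate number as a block, an added fold threshold, other list tests and leaving out each library. Scalings by median ratio or quantiles, removal of mitochondrial, ribosomal protein and immunoglobulin genes, a stricter filter and library weights were added after seeing the data. The fit with library weights used the gene-by-gene method of limma.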

Results

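Gene expression was measured by RNA sequencing in 6 tumours grown from HM1, a mouse ovarian cancer cell line, and sampled in an early tumour model. In 3 of them the cells carried a control short hairpin RNA (shControl), and in 3 a hairpin against the sialyltransferase ST3GAL3 (shST3GAL3). The comparison asked how loss of ST3GAL3 in the tumour cells altered the transcripts of the tumour, immune genes above all. Each library was given as TPM, a measure of relative transcript abundance corrected for gene length, which keeps no record of read number, so the depth of each library is unknown. Between 13930 and 14762 genes per library had a TPM of 1 or more, and 14207 genes were tested. Nothing in the labels says that the samples of a group came from separate mice, so p-values measure only the spread between these samples, which may be technical.

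St3gal3 (ENSMUSG00000028538, on chromosome 4 in GENCODE M21) was lower in the shST3GAL3 tumours, as a check of the labels. It stood at 14.03, 13.84 and 13.79 TPM in shControl 1, 2 and 3 and at 8.44, 6.77 and 7.49 TPM in shST3GAL3 1, 2 and 3. The means were 13.9 ± 0.127 and 7.57 ± 0.838 TPM (SD, n = 3 each), so that 54.5% of the control level was left. These are values of whole tumours, host cells included, so the level left in the tumour cells alone is unknown. The log2 fold change was -0.80 (SE 0.11), with all 3 values below those of the control group. For this gene, named in advance, the limma p was 0.000185 unadjusted and 0.348 adjusted over all genes. The adjusted p was 0.0337 in a fit with library weights chosen after the data were seen. An exact two-sided permutation test gave p = 0.1, the smallest that 3 against 3 samples allow.

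The other St3gal genes, which encode enzymes that also add sialic acid to galactose, did not pass the test over all genes. St3gal2 stood at 28.8 ± 2.48 TPM in shControl and 33.0 ± 1.07 in shST3GAL3 tumours (log2 fold change 0.19, SE 0.09). St3gal1 stood at 52.5 ± 2.55 and 52.9 ± 3.79 TPM (0.01, SE 0.08). Its sign turned under 3 other scalings of the libraries, which moved the median log2 fold change of all genes from 0.013 to between -0.046 and -0.005. The sign of St3gal1 also turned without shControl 2, shControl 3 or shST3GAL3 3 (-0.01, -0.01 and -0.04). Its log2 fold change was small against its SE, so no direction can be given. St3gal4 (-0.09, SE 0.11), St3gal5 (-0.29, SE 0.25) and St3gal6 (-0.35, SE 0.30) had lower means in the shST3GAL3 tumours. Without shST3GAL3 1 the log2 fold change was 0.02 for St3gal4 and 0.01 for St3gal6. Of the 11 sialyltransferase genes tested, 1 rose and 1 fell when adjusted over the list alone. These were St6galnac4, at 28.7 ± 1.60 and 37.7 ± 0.945 TPM (adjusted p = 0.0115 over the list), and St3gal3 itself (0.00204). Without shControl 2 or shST3GAL3 2, St6galnac4 did not pass, and 0 genes rose. The list as a whole was not called (camera adjusted p = 0.893), with a median log2 fold change of 0.01, a mean of -0.03 and a downward test direction.

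**Figure D1:**
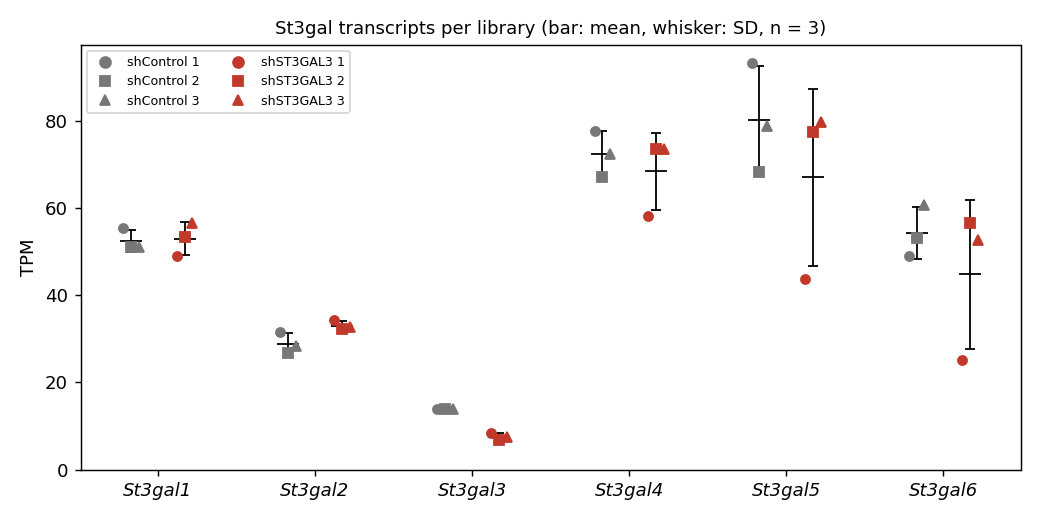
TPM (vertical axis, from 0) of the 6 St3gal genes (horizontal axis) in each library, grey for shControl and red for shST3GAL3, with the mean and SD of each group (n = 3). St3gal3 lies between 13.79 and 14.03 TPM in the shControl and between 6.77 and 8.44 TPM in the shST3GAL3 libraries. St3gal1 overlaps between the groups, and its log2 fold change of 0.01 turned sign, with the median of all genes, under 3 other scalings.

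Over all 14207 genes, 0 rose and 1 fell at an adjusted p under 0.05 (limma). The gene that fell was Gm1943 (ENSMUSG00000110528), a processed pseudogene in GENCODE M21, named here after its values were seen since the naming rule leaves predicted genes out. It stood at 33.19, 37.26 and 27.34 TPM in shControl 1, 2 and 3 and was listed at 0 in all 3 shST3GAL3 libraries (adjusted p = 0.000131). Its 174 nt transcript is identical to part of a transcript of the protein-coding gene Wdr70, so its level is uncertain. At an unadjusted p under 0.05 there were 1842 genes, 1305 higher and 537 lower, or 70.8% higher. That share was 54.1% with median-ratio scaling, 47.8% with quantile normalization and 62% without mitochondrial, ribosomal protein and immunoglobulin genes. All 3 shST3GAL3 values lay above all 3 shControl values for 2232 genes and below them for 1103, together 23.5% of the genes. The average over all ways of splitting the libraries into 3 and 3 is 10%. Genes in tissue vary together, so any 1 split can lie far from it, and the share was not computed for the other splits.

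Among the genes with the smallest p, those with higher values in the shST3GAL3 tumours included Marco, a scavenger receptor of macrophages, at 1.69 ± 0.234 TPM in shControl and 6.45 ± 0.297 in shST3GAL3 tumours (log2 fold change 1.47, SE 0.13, adjusted p = 0.0801). Serpina3g, a protease inhibitor of immune cells, stood at 75.1 ± 1.81 and 137 ± 15.6 TPM (0.85, SE 0.10, adjusted p = 0.241). Tigit, an inhibitory receptor of T and NK cells, stood at 17.8 ± 1.06 and 27.2 ± 0.888 TPM (0.59, SE 0.08, adjusted p = 0.38). Of the antibody variable genes, Igkv3-5 had a log2 fold change of 4.08 (SE 0.49), and Ighv1-50 was listed at 0 in all shControl libraries. Lower values were found for Appl2, an endosomal adaptor (80.1 ± 4.45 and 54.6 ± 3.62 TPM), Rnf128, a ubiquitin ligase (23.9 ± 1.68 and 14.8 ± 1.13 TPM), the cadherin Cdh18 (4.73 ± 0.478 and 1.92 ± 0.361 TPM) and Xlr (41.0 ± 3.49 and 24.8 ± 4.06 TPM). For each of these 9 genes the groups did not overlap, and none passed over all genes. Selection by the smallest p favours genes without overlap, so this adds no support. For Ighv1-50 the filter on low values made overlap impossible, since all shControl values were 0. With library weights Marco, Ighv1-50 and Serpina3g passed (adjusted p = 0.0286, 0.0286 and 0.0337), and Ighv1-50 also passed without shST3GAL3 1 (0.0169).

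Genes induced by interferon gamma, the main cytokine of activated T and NK cells, were higher as a set in the shST3GAL3 tumours. All 15 had a positive log2 fold change, with a median of 0.57, and for 13 the groups did not overlap. With adjustment over the list alone 11 rose, and over all genes 0 did. Socs1, a feedback inhibitor of cytokine signalling, stood at 5.54 ± 0.622 TPM in shControl and 10.1 ± 0.849 in shST3GAL3 tumours (log2 fold change 0.77, SE 0.12), and the GTPase genes Irgm2 (0.67, SE 0.12) and Gbp2 (0.73, SE 0.16) also rose over the list alone. The list was called by camera (adjusted p = 1.7e-10), but not with an estimated correlation (adjusted p = 0.426 with an estimated correlation). Medians against the shControl mean were 0.52, 0.80 and 0.41 in shST3GAL3 1, 2 and 3. Leaving out any 1 library left 9 to 13 genes passing when adjusted over the list alone.

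The MHC class I presentation genes, whose products load and show peptides to CD8 T cells, had a median log2 fold change of 0.41, and all 11 lay above the control range in all 3 shST3GAL3 tumours. All 11 rose when adjusted over the list alone, and 0 over all genes. Without shControl 3 or without shST3GAL3 2 that count was 0. The peptide transporter genes Tap1 (84.2 ± 5.63 and 122 ± 15.7 TPM) and Tap2 (53.3 ± 4.30 and 72.7 ± 7.18 TPM), with Tapbp (195 ± 13.2 and 263 ± 26.6 TPM), led the list. It was called by camera (adjusted p = 5.09e-08; adjusted p = 0.426 with an estimated correlation). The type I interferon list, of antiviral genes, had a median of 0.41 over 17 genes, all with positive values, and 0 passed over the list alone. Its medians were 0.42, 0.38 and 0.37 in shST3GAL3 1, 2 and 3 and 0.09, -0.51 and 0.48 in shControl 1, 2 and 3. The groups thus overlapped, with shControl 3 the highest. Oasl2 stood at 46.7 ± 12.4 and 70.5 ± 11.5 TPM. Its call (adjusted p = 0.00104; adjusted p = 0.439 with an estimated correlation) was lost without shControl 2, where the median was 0.12 and the adjusted p 0.139, and the median was 0.62 without shControl 3.

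**Figure D2:**
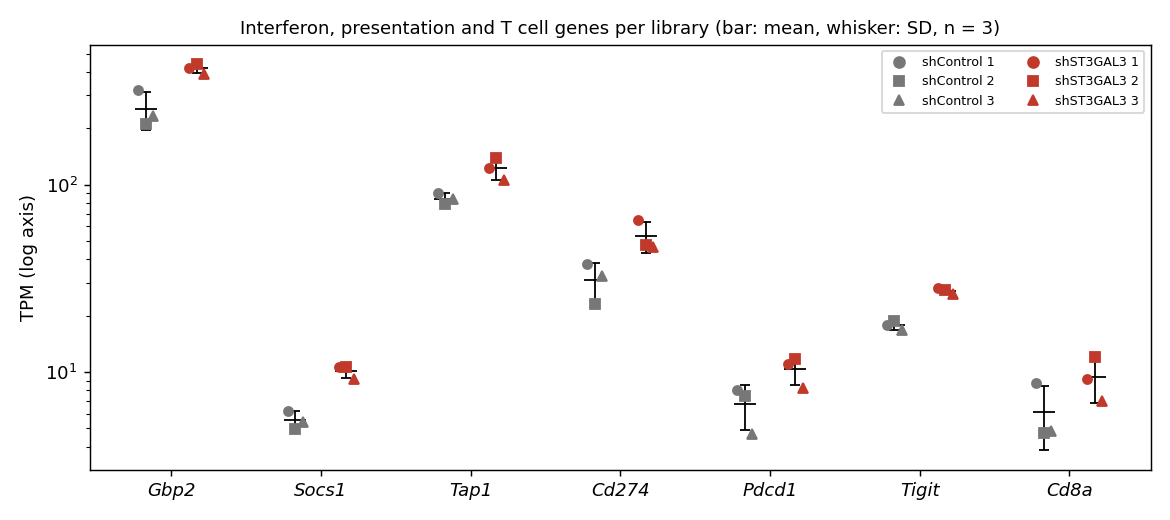
TPM on a log axis (vertical) of 7 interferon, antigen presentation and T cell genes (horizontal) in each library, grey for shControl and red for shST3GAL3, with the mean and SD of each group (n = 3). Socs1 has means of 5.54 and 10.1 TPM and Cd274 of 31.0 and 53.0 TPM without overlap between the groups, while Cd8a, at 6.10 and 9.40 TPM, overlaps.

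T cell genes were higher as a set, with a median log2 fold change of 0.64 and positive values for all 14 members. Cd4, the co-receptor of helper T cells, stood at 4.26 ± 0.901 TPM in shControl and 12.5 ± 6.58 in shST3GAL3 tumours, and the receptor constant gene Trbc2 at 13.6 ± 2.99 and 26.9 ± 8.39 TPM. Over the list alone 8 rose, and over all genes 0. The cytotoxic lymphocyte list had a median of 0.57, and 2 of 14 genes rose over the list alone, the granzyme gene Gzma (10.4 ± 2.91 and 23 ± 6.46 TPM) and the chemokine gene Ccl5 (54.2 ± 2.15 and 118 ± 42.8 TPM). Cd8a, the co-receptor of cytotoxic T cells, stood at 6.10 ± 2.28 and 9.40 ± 2.55 TPM (0.57, SE 0.27), with overlap. In the NK cell list, with a median of 0.45, 1 of 5 genes rose over the list alone, Il2rb (11 ± 1.41 and 20.1 ± 5.25 TPM). These lists were called by camera (adjusted p = 8.61e-07, 0.000208 and 0.023), each with an adjusted p = 0.426 with an estimated correlation. The medians of the T cell list were 0.98, 0.78 and 0.25 in shST3GAL3 1, 2 and 3. Those of the fibroblast and matrix list stood in the same order (2.78, 0.96 and 0.55). In shST3GAL3 3 the cytotoxic median was 0.19, against 0.27 in shControl 1. The NK cell median there was -0.01, against 0.18 in shControl 3. Over the list alone, the count of 8 T cell genes was 0 without any 1 shControl library or shST3GAL3 2, 1 without shST3GAL3 1 and 14 without shST3GAL3 3. The cytotoxic count of 2 ranged from 0 to 7 over the same fits, with 0 without shControl 1, shControl 2, shST3GAL3 1 or shST3GAL3 2, 1 without shControl 3 and 7 without shST3GAL3 3. The NK cell call was lost without shControl 2 (adjusted p = 0.053), shST3GAL3 1 (0.204, median 0.25) or shST3GAL3 2 (0.0577), and the median was 0.80 without shST3GAL3 3, where 4 of its genes passed over the list alone. Its count of 1 was 0 without shControl 2, shControl 3 or shST3GAL3 2.

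The T cell checkpoint list held mostly genes of inhibitory and co-stimulatory receptors and their ligands. Entpd1, an enzyme gene, and Tox, a transcription factor gene, were also members. The list had a median log2 fold change of 0.59, positive values for all 13 genes and no overlap between the groups for 10. Over the list alone 7 rose, and over all genes 0. Tigit led the list (adjusted p = 0.00354 over the list alone). Cd274, which encodes PD-L1, stood at 31.0 ± 7.25 TPM in shControl and 53.0 ± 10.0 in shST3GAL3 tumours (0.76, SE 0.20), and Icos and Entpd1 also rose over the list alone. Pdcd1, which encodes PD-1, stood at 6.71 ± 1.81 and 10.4 ± 1.85 TPM (0.57, SE 0.22, limma adjusted p = 0.38). The regulatory T cell list had a median of 0.80 and 0 of 7 genes passing over the list alone. Its marker Foxp3 stood at 1.22 ± 0.261 and 3.02 ± 1.63 TPM, and Ctla4 at 3.12 ± 0.462 and 8.35 ± 4.81 TPM. Both lists were called by camera (adjusted p = 2.74e-06 and 0.00417; adjusted p = 0.426 with an estimated correlation for each). The checkpoint count of 7 was 1 without shControl 2 or shControl 3, 2 without shControl 1 or shST3GAL3 2 and 5 without shST3GAL3 1. The regulatory T cell median was 0.52 without shST3GAL3 1, and its count of 0 was 1 without shST3GAL3 1, 4 without shST3GAL3 2 and 2 without shST3GAL3 3.

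Macrophage genes had a median log2 fold change of 0.51 with positive values for all 12, and 0 passed over the list alone. The growth factor receptor gene Csf1r stood at 53.0 ± 11.9 TPM in shControl and 107 ± 44.7 in shST3GAL3 tumours, and the complement gene C1qb at 300 ± 17.8 and 442 ± 114 TPM. Adgre1, which encodes F4/80, stood at 18.5 ± 3.97 and 35.4 ± 20.6 TPM (0.76, SE 0.40), with overlap. The macrophage medians were 0.97, 0.54 and 0.11 in shST3GAL3 1, 2 and 3, the last close to 0.10 in shControl 1. The inflammatory (M1-type) list had a median of 0.52, with Nos2 at 7.40 ± 2.97 and 26.9 ± 20.3 TPM, and the dendritic cell list a median of 0.58, with Itgax at 31.8 ± 5.35 and 47.7 ± 7.24 TPM. The chemokine list had a median of 0.69, with Cxcl14 at 22.7 ± 8.28 and 109 ± 91.8 TPM. In shST3GAL3 3 the dendritic cell median was 0.12, against 0.27 in shControl 2. The chemokine median there was 0.16, against 0.18 in shControl 1. In none of these lists did a gene pass over the list alone. Camera called all 4 (adjusted p = 5.96e-05 for macrophage, 0.00404 for M1-type, 0.00298 for dendritic cell and 0.000599 for chemokine genes; adjusted p = 0.426 with an estimated correlation for each). Without shST3GAL3 1 the medians were 0.31, 0.21, 0.31 and 0.30, and the calls of the M1-type and dendritic cell lists were lost (adjusted p = 0.205 and 0.0772). The M1-type call was also lost with library weights (adjusted p = 0.0723, median 0.22). Without shST3GAL3 3 the M1-type median was 0.82, and 10 macrophage, 1 M1-type, 5 dendritic cell and 6 chemokine genes passed over the list alone. Without shST3GAL3 1 there were 1 dendritic cell and 2 chemokine genes. The alternative (M2-type) macrophage list, with Mrc1 at 62.2 ± 10.8 and 91.1 ± 28.6 TPM, and the neutrophil list, with Mmp8 at 2.92 ± 1.54 and 6.94 ± 2.17 TPM, were not called (adjusted p = 0.0756 and 0.308). The M2-type list was called without shControl 1, shST3GAL3 2 or shST3GAL3 3 (adjusted p = 0.0448, 0.0394 and 0.0133), while without shST3GAL3 1 its median of 0.51 became -0.01 (adjusted p = 0.722). The neutrophil list was called without shST3GAL3 2 (0.0455), and its median was -0.16 without shST3GAL3 1.

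The MHC class II genes, which present antigen to CD4 T cells, had a median log2 fold change of 0.76, and 7 of 8 rose over the list alone, with 0 over all genes. H2-Aa stood at 421 ± 82.0 TPM in shControl and 770 ± 214 in shST3GAL3 tumours, and H2-Eb1 at 349 ± 80.2 and 670 ± 197 TPM. The list was called by camera (adjusted p = 2.11e-05; adjusted p = 0.426 with an estimated correlation). The count of 7 was 0 without shControl 1, shControl 3, shST3GAL3 1 or shST3GAL3 2. The B and plasma cell list had a median of 2.33 over 4 tested genes, with 0 passing over the list alone. Igkc, the antibody kappa constant gene, stood at 13.78, 40.48 and 2.22 TPM in shControl 1, 2 and 3 and at 3772.44, 288.6 and 36.44 TPM in shST3GAL3 1, 2 and 3. This list was called (adjusted p = 0.0103; adjusted p = 0.426 with an estimated correlation), with a median of 0.93 without shST3GAL3 1 and 0.76 without the filter on low values, which removed 6 of its 10 genes. All 4 genes passed over the list alone without shST3GAL3 3. The list median was 0.34 in shST3GAL3 3 and 0.75 in shControl 2.

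Markers of the tumour stroma were higher as sets, as were globin genes and the genes of handling stress. The fibroblast and matrix list had a median log2 fold change of 1.43, with 14 of 15 genes above the control range in all 3 shST3GAL3 tumours, and 4 rose over the list alone. Pdgfra, a growth factor receptor of fibroblasts, stood at 5.66 ± 1.21 TPM in shControl and 23.1 ± 17.4 in shST3GAL3 tumours, and the collagen gene Col6a1 at 141 ± 19.8 and 301 ± 119 TPM. The endothelial list had a median of 1.04, and 8 of 10 genes rose over the list alone, among them Vwf (8.10 ± 0.974 and 17.9 ± 8.29 TPM) and Cldn5 (5.76 ± 2.69 and 11.8 ± 2.11 TPM). In the erythroid list, with a median of 0.79, 3 of 4 globin genes rose over the list alone, with Hba-a1 at 27.4 ± 5.32 and 52.7 ± 10.6 TPM. In the handling stress list, of early response genes, the median was 0.30 and 0 of 11 passed over the list alone. Its medians were 0.70, 0.20 and 0.19 in shST3GAL3 1, 2 and 3 and 0, -0.04 and 0.03 in shControl 1, 2 and 3. A difference in handling between the groups is therefore not excluded. Junb stood at 178 ± 10.7 and 282 ± 86.7 TPM. Camera called all 4 lists (adjusted p = 9.18e-08, 4.51e-06, 0.00104 and 0.0023; adjusted p = 0.426 with an estimated correlation for each). Fibroblast medians were 2.78, 0.96 and 0.55 in shST3GAL3 1, 2 and 3. The erythroid median was 0.41 without the filter on low values, which removed 3 of its 7 genes. The handling stress median was 0.45 without shST3GAL3 2. Without shST3GAL3 1 the fibroblast median was 0.72, with 12 genes passing over the list alone, and the endothelial median 0.64. The fibroblast count of 4 and the endothelial count of 8 were both 0 without any 1 shControl library or shST3GAL3 2, and the fibroblast count was 14 without shST3GAL3 3.

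The adipocyte list was not called (camera adjusted p = 0.152), although Cfd (2.79 ± 2.82 and 20.5 ± 11.2 TPM) and Fabp4 (9.18 ± 2.22 and 38.7 ± 27.7 TPM) rose over the list alone. Only 4 of its 10 genes passed the filter on low values, and without that filter the list was called (adjusted p = 0.00176). The count of genes that rose was 0 without shControl 2, shControl 3, shST3GAL3 1 or shST3GAL3 2, and 1 without shControl 1. The skeletal muscle list was not called either (adjusted p = 0.256), and its medians were -0.94, 3.02 and 0.91 in shST3GAL3 1, 2 and 3. Without shControl 1 or shST3GAL3 1 it was called (adjusted p = 0.0121 and 0.00222). In the keratinocyte, normal ovary and pancreas and liver lists fewer than 3 genes were tested, so no list test was made. Krt10 stood at 4.27 ± 0.806 and 3.36 ± 0.440 TPM, Star at 1.30 ± 0.108 and 1.28 ± 0.191 TPM and Cela1 at 59.0 ± 2.27 and 48.9 ± 9.44 TPM.

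Cell cycle genes were lower as a set in the shST3GAL3 tumours, mostly in shST3GAL3 1. All 20 had a negative log2 fold change, with a median of -0.25, and 0 passed over the list alone. The proliferation marker Mki67 stood at 39.9 ± 1.77 TPM in shControl and 28.9 ± 6.68 in shST3GAL3 tumours (-0.48, SE 0.16), and the mitotic kinase gene Aurka at 37.8 ± 2.90 and 28.9 ± 3.72 TPM (-0.38, SE 0.12). The hypoxia and glycolysis list had a median of -0.23, with Pgk1 at 1370 ± 131 and 1150 ± 76.2 TPM and 0 of 16 genes passing over the list alone. Of its genes 6 had a positive log2 fold change. Its medians were 0.02, -0.18 and -0.17 in shST3GAL3 1, 2 and 3 and -0.07, 0.17 and -0.11 in shControl 1, 2 and 3. Thus shST3GAL3 1 lay within the control range. Both lists were called by camera (adjusted p = 2.96e-06 and 0.0103; adjusted p = 0.426 with an estimated correlation for each). Cell cycle medians were -0.65, -0.05 and -0.13 in shST3GAL3 1, 2 and 3 and 0.02, 0.09 and -0.11 in shControl 1, 2 and 3. Thus shST3GAL3 2 lay within the control range and shST3GAL3 3 just below it. The median log2 fold change was -0.10 without shST3GAL3 1. That library stood apart from the rest and also had the highest fibroblast, endothelial, macrophage and T cell medians, at 2.78, 1.90, 0.97 and 0.98. The hypoxia call was lost without shControl 2 (adjusted p = 0.158, median -0.10), shST3GAL3 2 (0.0737, median -0.13) or shST3GAL3 3 (0.174, median -0.13).

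The epithelial and ovarian tumour list was not called (camera adjusted p = 0.562), with a median of 0.01, a mean of 0.07 and a downward test direction. Of its 7 tested genes 4 had a positive log2 fold change. Muc1, the member with the smallest p, stood at 1.21 ± 0.533 TPM in shControl and 3.84 ± 1.93 in shST3GAL3 tumours, without overlap (1.08, SE 0.35). Krt19, a keratin of epithelial cells, went the other way, at 965 ± 95.2 and 642 ± 230 TPM, also without overlap (-0.66, SE 0.28). With a filter of at least 5 TPM, chosen after seeing the data, the list was called lower (median -0.38, adjusted p = 0.0463), and without shST3GAL3 3, 3 genes fell over the list alone. Without shST3GAL3 1, 1 gene rose over the list alone. The mesenchymal transition list (adjusted p = 0.0729), with Mmp2 at 17.6 ± 6.62 and 105 ± 115 TPM, was not called, but was without shControl 1, shST3GAL3 2 or shST3GAL3 3 (0.0448, 0.0465 and 0.0476). Neither were the lists of sialic acid metabolism (adjusted p = 0.372), selectins and their ligands (0.308) and Siglecs, the sialic acid receptors of immune cells (0.0729), the last of which was called without shST3GAL3 3 (0.0214). Neu1, a sialidase gene, stood at 16.4 ± 1.98 and 21.3 ± 3.57 TPM, and Selplg, the gene of a selectin ligand, at 26.6 ± 1.76 and 48.1 ± 22.7 TPM. Siglece stood at 3.81 ± 0.998 and 4.61 ± 0.777 TPM (0.23, SE 0.19), within the spread between replicates, and Cd22 at 5.26 ± 1.31 and 8.07 ± 1.75 TPM.

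**Figure D3:**
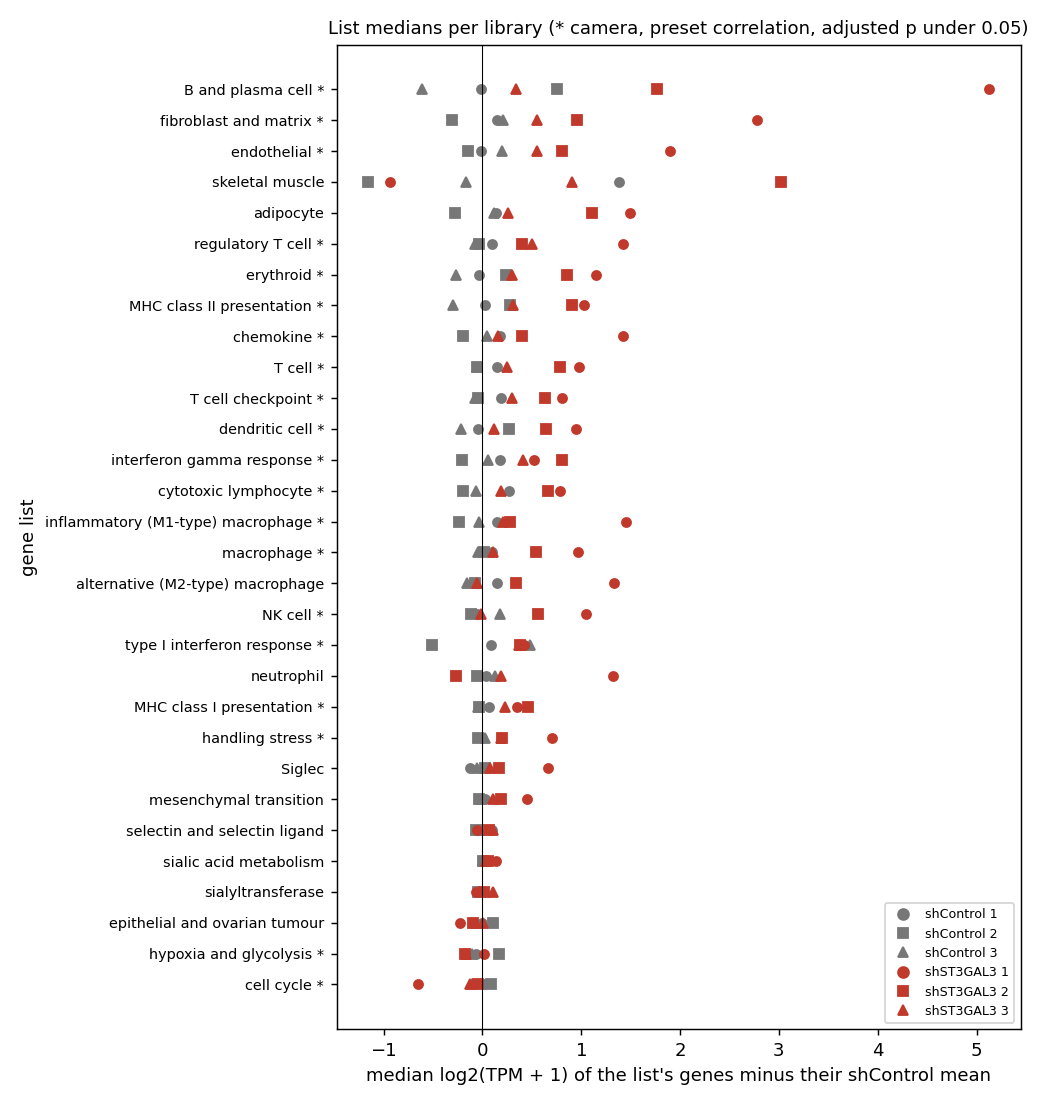
Median log2(TPM + 1) of each tested list's genes minus their shControl mean (horizontal axis) for the 30 lists (vertical axis) in each library, grey for shControl and red for shST3GAL3, with a star for lists called by camera with the preset correlation. The fibroblast and matrix list lies at 2.78, 0.96 and 0.55 in shST3GAL3 1, 2 and 3, and the interferon gamma list at 0.52, 0.80 and 0.41.

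In all, camera called 20 of the 30 tested lists, 18 higher and 2 lower. With an estimated correlation 0 were called, with an adjusted p of 0.426 or more for each of the 20 and 0 lists at an unadjusted p under 0.05. The rotation test fry also called 0 (smallest adjusted p = 0.17), with 5 lists at an unadjusted p under 0.05. The library shST3GAL3 1 stood apart from the rest, at 64.6 on the first principal component (56.8% of the variance) where the other libraries lay between -24.3 and 8.7.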

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

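The scalings, the stricter filter and the library weights were chosen after seeing the data. Alternatives that need counts were not run, namely the other count model, voom, and both other normalizations. The alternative filter on a CPM of 1 in 3 libraries also needs counts and was not run. Its counterpart in TPM was the filter used, and the limma fit on log2(TPM + 1) was the analysis itself. Depth is unknown and limits what low values can show.

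St3gal3 was lower in every alternative, and passed the threshold only with library weights (log2 fold change -0.89, adjusted p = 0.0337), which were 0.2 for shST3GAL3 1 and 2.43 for shST3GAL3 2. Against 0 genes higher and 1 lower, 1 was higher with a pseudocount of 0.1, and 5 were higher and 3 lower with library weights. With protein-coding genes only 0 were lower, since Gm1943 was then not tested. It was called in every alternative that tested it. Leaving out each library in turn gave 0 to 2 genes higher and 1 to 2 lower, -0.87 to -0.73 for St3gal3 and 17 to 23 lists called. Against 20 lists, 0 were called with an estimated correlation and 0 by fry. With all 6 libraries, the lists newly called were M2-type, Siglec and adipocyte without a filter, M2-type and mesenchymal with quantile normalization or the replicate block, epithelial with the stricter filter and muscle with library weights. The M1-type call was lost with library weights (adjusted p = 0.0723), and with them the medians of the fibroblast, chemokine and cell cycle lists were 0.92, 0.42 and -0.09. Apart from the correlation set for camera, the cause of these differences was not tested.

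Values reversed as follows, none of them called. St3gal1 stood at -0.01 with median-ratio scaling, -0.02 with quantile normalization and -0.01 without mitochondrial, ribosomal protein and immunoglobulin genes, and leaving out 1 library gave -0.04 to 0.06. Star stood at 0.06 with library weights and turned without shControl 3 or shST3GAL3 1, and St3gal4 and St3gal6 turned without shST3GAL3 1. Leaving out 1 library gave -0.07 to 0.05 for Star, -0.14 to 0.02 for St3gal4 and -0.56 to 0.01 for St3gal6. The test direction of the sialyltransferase list turned without a filter (median 0.01) and without shST3GAL3 1, that of the neutrophil list with library weights (-0.11) and without shST3GAL3 1, and that of the skeletal muscle list without shControl 2 or shST3GAL3 2. Leaving out 1 library gave medians of -0.04 to 0.06, -0.16 to 0.69 and -0.16 to 1.97 for these lists. The cause was not tested.

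The replicate numbers gave no sign of a pairing. Deviations of same-numbered libraries correlated at 0.01, -0.08 and 0.04, and shControl 1 correlated best with shST3GAL3 2 (0.13). Deviations from means of 3 libraries cannot exclude a pairing or a shared batch. With the number as a block, 0 genes were higher and 1 lower, 22 lists were called, and St3gal3 stood at -0.80 (adjusted p = 0.332).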

Other observations

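The gene families below, the values per chromosome, the scaling test and the count of genes over other splits were chosen after the results were seen. Immunoglobulin genes summed to 73.1, 216.7 and 30.8 TPM in shControl 1, 2 and 3 and to 17428.8, 1058.6 and 213.2 TPM in shST3GAL3 1, 2 and 3, so that shST3GAL3 3 lay within the control range. Ighg1, an antibody heavy chain constant gene, reached 2957.1 TPM in shST3GAL3 1, 126.8 in shST3GAL3 2 and 21.5 in shST3GAL3 3, against 0.68, 22.47 and 1.65 TPM in the shControl libraries. T cell receptor variable genes summed to 64.6, 34.6 and 41.2 TPM in the shControl and 104.1, 113.1 and 51.7 TPM in the shST3GAL3 libraries. Mitochondrially encoded transcripts made up 3.84%, 3.75% and 3.97% of the TPM in the shControl and 3.12%, 3.39% and 3.05% in the shST3GAL3 libraries, without overlap.

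Of 12 families grouped by gene symbol, camera called 11, and 0 with an estimated correlation (smallest adjusted p = 0.227, with 1 at an unadjusted p under 0.05). Some families share genes with the lists above and are no separate support for them. The interferon-inducible GTPase genes overlap with the interferon gamma list, and the collagen genes with the fibroblast and matrix list. Interferon-inducible GTPase genes had a median log2 fold change of 0.54, with 14 of 17 above the control range in all shST3GAL3 libraries (adjusted p = 0.315 with an estimated correlation). Of 24 collagen genes 14 lay above that range, with a median of 1.01 (0.318), and of 12 non-classical MHC class I genes 8, with H2-T23, which presents leader peptides to NK cells, at 367 ± 27.5 and 476 ± 22.7 TPM (0.315 for the family). Of 8 mast cell protease genes 4 lay above that range, with a median of 1.20 (0.315). Mcpt8 had the highest control mean of them and a lower mean in the shST3GAL3 tumours (48.9 ± 1.32 and 42.0 ± 9.33 TPM), while Mcpt1 stood at 6.03, 6.68 and 3.27 TPM in shControl 1, 2 and 3 and at 80.25, 17.8 and 15.75 TPM in shST3GAL3 1, 2 and 3 (limma adjusted p = 0.38). Among cytoplasmic ribosomal protein genes, 27 of 75 lay below the control range, with a median of -0.09, and among keratins 2 of 8, with a median of -0.30 (adjusted p = 0.318 and 0.315 with an estimated correlation). The other called families were antibody and T cell receptor variable genes, higher, and respiratory chain, mitochondrially encoded and Zfp genes, lower, while proteasome genes were not called.

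With 3 against 3 libraries there are 10 splits, too few for a share under 0.05. The real split called 1 gene and the highest other split 2, with as many as the real one in 8 of the 10 splits. At an unadjusted p under 0.05 the real split had 1842 genes and the highest other 775. For gene lists the real split called 20 and the highest other 22, with as many in 3 of the 10 splits. The camera adjusted p of the interferon gamma list was 1.7e-10 in the real split. Other splits also called that list, at 5.95e-07, 4.04e-05, 0.000541, 0.00832 and 0.0371, while the rest did not (0.0628 to 0.763). Camera with the preset correlation thus called this list also in splits that mix the groups.

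The interferon gamma and MHC class I lists were together 0.50 higher (SE 0.12) in the shST3GAL3 tumours. Scaling of TPM to a fixed total as the whole cause is argued against, since the difference was 0.46 or more after median-ratio scaling and quantile normalization. A larger share of host stroma and leukocytes could contribute. A host score of fibroblast, endothelial, macrophage and T cell lists was 1.63, 0.78 and 0.36 above the control mean in shST3GAL3 1, 2 and 3. The score of the interferon gamma and MHC class I lists, at 0.52, 0.66 and 0.32 above it, did not stand in that order. With the host score as a covariate the difference was 0.38 (SE 0.19, 95% interval -0.23 to 0.99), and the slope of the host score was 0.13 (SE 0.16). Host content and an effect of the knockdown within cells therefore cannot be told apart with 6 libraries. An effect of the knockdown stays an untested hypothesis.

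Protein-coding genes of chromosome 15, chosen for their low median, had a median log2 fold change of -0.07 in the shST3GAL3 tumours, with 66.9% of 499 negative, while chromosomes 10 and 16 had medians of 0.09 each, with 35.8% and 32.9% negative. The chromosome 15 shift against the other autosomes was 0 in each shControl library and -0.19, -0.10 and -0.04 in shST3GAL3 1, 2 and 3, where the host score was 1.63, 0.78 and 0.36. The shifts stood in the same order by size on chromosomes 10 and 16, at 0.12, 0.04 and 0.02 on each, and on chromosome 4, at 0.09, 0.03 and 0.01. They did not on chromosome 13, at -0.06, -0.04 and -0.05, and on X, at -0.11, -0.04 and -0.05. DNA copies were not measured, and no explanation was tested.

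Gm1943, the only gene called over all genes, may owe its values to reads shared with a near-identical expressed gene, Wdr70. Its 174 nt transcript matched a Wdr70 transcript at 100% identity over its whole length, and Wdr70 stood at a mean of 56.9 TPM in shControl and 53.4 in shST3GAL3 tumours. Shared reads leave open why the 0 followed the group in all 3 shST3GAL3 libraries, and whether the groups were quantified in different runs or with different settings is also open, although all 6 files list the same genes and lengths. At a minimum of 5 TPM, 3 genes were listed at 0 throughout 1 group and expressed throughout the other: Gm1943, the pseudogene Gm6916 (0 in shControl; 13.32, 5.53 and 11.67 TPM in shST3GAL3 libraries) and Ighv1-50. No biological explanation was tested.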
